A study of Mus musculus with 2 samples.

How the data were processed

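Single-cell RNA was measured with the 10x Genomics 3' version 3 chemistry in enzymatically dissociated whole aorta of Ldlr-/- mice, 1 library per treatment. The deposited matrices hold raw UMI counts for 32285 genes, made by the authors with Cell Ranger 7.1.0 per the file headers. The submitters' notes also name Seurat and the mm10 genome without a role, and do not state whether intronic reads were counted. Every deposited barcode had at least 500 UMIs. Of the gene identifiers, 32158 matched GENCODE mouse release 21 on GRCm38, from which positions were taken.

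Cells were kept with at least 500 detected genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. This left 20076 of 26339 barcodes in the agonist and 18103 of 25933 in the isotype library, with median mitochondrial shares of 4.06% and 4.42%. Doublets were scored with an own implementation of Scrublet's algorithm. It used 2 simulated doublets per cell, an expected rate of 0.008 per 1000 barcodes, and a threshold at the minimum between the modes of the simulated scores. It removed 790 (3.94%) and 464 cells (2.56%), against expected rates of 21.1% and 20.7%. It detected 42.6% and 33.0% of simulated doublets, so doublets remain.

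Counts were scaled to 10000 per cell and log1p transformed, without correction for batch or RNA from other cells. 2000 variable genes, 30 principal components, 15 exact nearest neighbours with shared-neighbour weights, and Leiden clustering at resolution 1 (seed 0) gave clusters over both libraries together. Clusters were named from marker lists written beforehand. The class with most markers among the 10 leading genes (genes in at least 10% of the cluster's cells) won if at least 3 of its markers were 2-fold higher. On ties the class needed at least 5 such markers. This naming rule was chosen after the clusters were seen, and names such as macrophage-like rest on markers alone. As an exception, 3 genes of T cell precursors among the leading genes gave that name: cluster 21 had 3 of them and 4 T cell genes, and would otherwise have been T cell-like, and cluster 4, called modulated smooth muscle, was tied. Clusters 8 and 13 (1234 and 805 cells) had no marker among their leading genes, and the rule for ties named them contractile smooth muscle from 7 and 15 markers. Clusters with leading genes of more than 1 lineage, 144 and 151 cells, were left out, which left 19142 and 17488. Macrophage-like cells were re-clustered with 20 components at resolution 0.6 into states. Their unnamed state of 52 cells stays in the denominator.

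With 1 library per group no test between treatments was possible, and cells were not used as replicates. Shares have exact Clopper-Pearson 95% intervals, and ratios have intervals from the exact binomial of the counts given their sum. For each class the UMIs of a gene were summed per library and divided by the class's total, in counts per 1000000 UMIs (CPM). The log2 ratio used a pseudocount of 1 CPM. A count of 0 was taken to allow 3 counts. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs.

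The main comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. Trem2, Tyrobp and Ldlr were always named. Others needed at least 100 UMIs, at least 20 CPM in the higher library, and a ratio whose interval excludes 1. The 12 furthest higher and 12 furthest lower were named in macrophage-like and foamy-like cells, and 6 and 6 in other classes. Genes without a usual symbol, mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor genes, Xist and the 4 Y genes were left out; other sex-linked genes such as Tsix were not. Genes with at least 0.5 times the difference, in the same direction, in the other classes pooled were set apart, as were genes with 25% or more of their UMIs in 1 cell of the higher library. 40 gene lists were scored by the median log2 ratio of members with at least 50 UMIs, with an interval from 1000 Poisson redraws. The percentile places that median among 10000 random lists matched in 20 bins of mean CPM and only describes these libraries. A list is described when it was fixed for a class's main question or lies at or below percentile 2.5 or at or above 97.5.

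Sex calls, and the values within female-called and male-called cells, were chosen after seeing the data. So were the values without the cell with most UMIs of each gene, without cluster 25, in clusters 4, 7, 10 and 20 alone, and in state clusters 2 and 3 alone. The shares, list medians and genes given within single clusters or within the resident-like, cavity-like and inflammatory-like states were chosen then too, as were the T cell-like share with cluster 21 and the macrophage-like share of cells outside smooth muscle. Prespecified alternatives were a looser cell filter (at least 200 genes and 500 UMIs, at most 20% mitochondrial UMIs), at most 5% mitochondrial UMIs, no doublets removed, Leiden resolutions 0.5 and 2, and each library clustered on its own. Others were macrophages re-clustered without the foamy genes, median-of-ratios and TMM factors, means over cells, thinned cells, a pseudocount of 10 CPM, list minimums of none and 200 UMIs, cells with both Trem2 and Gpnmb, and thinning to 2000 UMIs or not at all. The log2 scaling factor, agonist over isotype, lay between -0.078 and -0.0075 over the classes. Dividing by it raised the log2 ratios by that size.

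The procedure was tested on simulated data with known fold differences, drawn as independent Poisson counts. These lack the variation between cells of the real data. The rates therefore check the calculation and are not error rates of the reported values. In 50 genes per size, the interval excluded 1 for 94% at a log2 ratio of -1 and 100% at 1, 2 and -2 in macrophage-like cells (8569 genes), and for 98 to 100% in foamy-like (6033 genes) and T cell-like cells (4972 genes). It excluded 1 for 5.17%, 5.67% and 6.85% of unchanged genes in these classes. Among 200 random lists, 4.50%, 4.00% and 2.50% met the percentile rule. In the real data 16 of 38 lists met it in macrophage-like cells.

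Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16, used for the TMM factor alone.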

Results

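Single-cell RNA of whole aorta was measured in Ldlr-/- mice, which lack the low-density lipoprotein receptor and form plaques on a high fat diet. 1 library came from treatment with AL002a, an antibody that activates the lipid-sensing receptor Trem2, and 1 from an isotype control antibody. Both antibodies were given weekly at 40 mg/kg for 8 weeks, after 8 weeks of diet. The agonist library held 26339 barcodes and 102849586 UMIs (unique molecular identifiers, the unit of the counts), and the isotype library 25933 barcodes and 79191743 UMIs. Cells passing the cell filter had a median of 3377.5 UMIs in the agonist and 2681 in the isotype library. There were no replicates, so no difference between the treatments could be tested. All intervals are at 95% and cover counting error only: exact for shares and ratios, and from Poisson redraws for list medians.

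Female and male cells were mixed in opposite proportions in the libraries. Cells with a UMI of Xist, the RNA of the inactive X chromosome, and none of 4 Y genes (Ddx3y, Eif2s3y, Uty, Kdm5d) were called female, and the reverse male. Female-called cells made up 32.7% of called cells in the agonist library (31.8 to 33.5) and 77.7% in the isotype library (77.0 to 78.4). No call was possible in 37.5% and 27% of cells, and 1.68% in each library had both markers, all left out within a sex. Cells with both were 7.79% and 2.94% of Xist-positive and 3.94% and 9.55% of Y-positive cells, higher for the rarer sex. The labels give neither sex nor number of mice, so values by sex are given too. 3 values in brackets after a gene or list are the log2 ratio of agonist over isotype in all, female-called and male-called cells. Few means 3 or fewer UMIs of that sex in a library.

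Macrophages took a larger share of the aorta in the agonist library and T cells a smaller one, though not in female-called cells. Whether the antibody altered the cellular make-up of the diseased aorta was the first question. Macrophage-like cells made up 8.19% against 5.91%, ratio 1.39 (1.28 to 1.50), and the ratio was 1.43 and 1.45 in female-called and male-called cells. T cell-like cells made up 2.87% against 4.51%, ratio 0.638 (0.571 to 0.712), with 1.05 and 0.385 in the same order. With cluster 21, named T cell precursors, counted among them, the ratio was 0.809 (0.863 and 0.637 by sex). Of all cells, T cell-like cluster 10, led by the naive T cell gene Lef1, had a ratio of 0.531 (0.723 and 0.282), and cluster 20, led by Il23r and Il17a, 0.926 (1.56 and 1.05).

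Pooled over sexes, the shares of smooth-muscle-like cells differed less than those of macrophage-like and T cell-like cells. Contractile smooth-muscle-like cells made up 40.4% against 44.5%, ratio 0.909 (0.880 to 0.938), with 0.876 and 0.944 in female-called and male-called cells. The ratio was 1.02 when each library was clustered on its own. Modulated smooth-muscle-like cells, which have lost contractile genes, made up 11.9% against 13.4%, ratio 0.890 (0.840 to 0.943), with 0.719 and 1.01. Fibroblast-like cells made up 11.6% against 9.40%, ratio 1.24 (1.16 to 1.32), with 1.68 and 1.28, but 1.00 to 1.15 over the prespecified alternatives, the lowest with at most 5% mitochondrial UMIs. Of these cells, cluster 25, led by Cyp26a1 and Cthrc1, held 166 cells in the agonist and 12 in the isotype library, and 157 of the 166 were female-called. Endothelial-like cells made up 2.14% against 1.72%, ratio 1.24 (1.07 to 1.45), with 1.09 and 1.36, and the ratio was 0.759 when each library was clustered on its own.

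Among other leukocytes, monocyte-like cells had a ratio of 1.23 (1.26 and 1.56 by sex, 0.986 with at most 5% mitochondrial UMIs), NK-like cells 1.51 (1.54 and 0.888) and B cell-like cells 1.13 (1.88 and 0.577). Neutrophil-like cells had a ratio of 1.63 (1.75 and 2.17), dendritic-like cells 1.07 (1.06 and 0.630) and plasma-cell-like cells 0.25 (0.579 and 0.114). Schwann-like cells had 0.371 (0.124 and 1.94), pericyte-like cells 1.66 (1.76 and 4.77) and mesothelial-like cells 1.49 (2.34 and 1.06). Proliferating, erythroid-like and lymphatic endothelial-like cells had ratios of 1.45, 1.03 and 0.930. Cluster 21, led by Arpp21, Rag1 and Dntt, genes of T cell precursors, held 270 cells against 138.

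**Figure D1:**
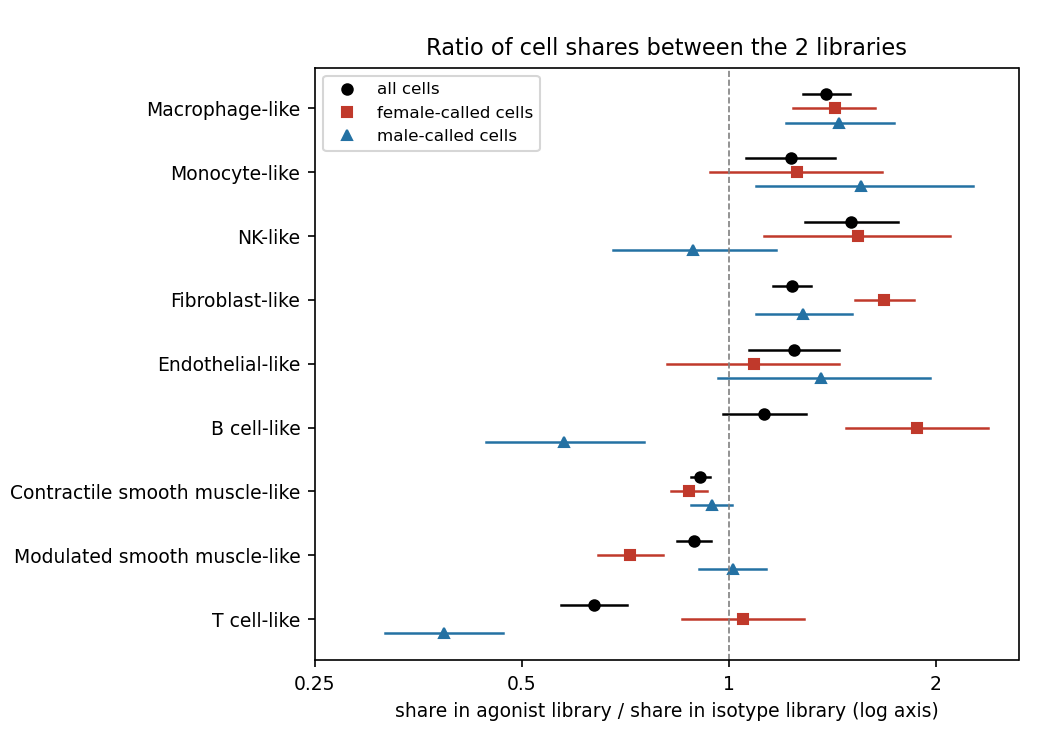
Share of cells in the agonist library divided by the share in the isotype library (log axis) for 9 classes of cells, in all, female-called and male-called cells, with lines for the counting interval. The macrophage-like ratio lay at 1.39, 1.43 and 1.45, and the T cell-like ratio at 0.638, 1.05 and 0.385.

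Foamy macrophages, the lipid-laden cells that carry Trem2, formed a similar share of macrophages in both libraries, but 1 of their 2 clusters did not. The antibody's target made the macrophage states the next question. The foamy-like state held 38.3% against 36.4%, ratio 1.05 (0.924 to 1.2), 1.00 and 1.10 by sex. The ratio was 0.903 and 0.908 under the looser cell filter and at most 5% mitochondrial UMIs. Its state cluster 2 was led by Npy and named from 3 markers. It held 22.4% against 17.9% of macrophage-like cells, ratio 1.25 (1.05 to 1.51), with 0.953 and 1.66 by sex. State cluster 3, led by Fabp5 and Gpnmb (11 markers), held 15.9% against 18.5%, ratio 0.859 (0.708 to 1.04), with 1.09 and 0.754. The inflammatory-like state, led by Il1b and Cxcl1, held 36.8% against 33.7%, ratio 1.09 (0.955 to 1.25). The resident-like state, led by Lyve1 and Cd163, held 19.6% against 22.7%, ratio 0.864 (0.727 to 1.03), and the cavity-like state, led by Ear2, held 3.25% against 5.32%, ratio 0.611 (0.409 to 0.911).

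After thinning to 1000 UMIs per cell, Trem2 was seen in 44.6% (42.2 to 47.1) against 41.6% (38.6 to 44.7) of macrophage-like cells, and its partner Tyrobp in 78.6% (76.5 to 80.6) against 75.3% (72.6 to 77.9). Gpnmb was seen in 19.1% (17.2 to 21.2) against 22% (19.5 to 24.6), Il1b in 17.9% (16.0 to 19.8) against 14.8% (12.7 to 17.1) and Cd74, the MHC class II chaperone, in 54.7% (52.2 to 57.1) against 50.1% (47.1 to 53.2). Spp1 was seen in 51.7% (49.2 to 54.2) against 50.8% (47.7 to 53.9). In T cell-like cells, which should largely lack these genes, Trem2 was seen in 0 of 550 agonist cells, which allows up to 0.668%, and in 0.254% of isotype cells. There, Tyrobp was seen in 1.09% and 1.02%, Gpnmb in 0.545% and 0.127%, Cd74 in 4.0% and 3.43%, and Spp1 in 25.3% and 17.9%. Median depths before thinning were 3962 and 2759 UMIs in macrophage-like and 2048 and 2252 in T cell-like cells.

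Trem2 RNA itself differed little in macrophages. It was at 0.13 there and at 0.22 in the other classes pooled, and Tyrobp at 0.11 and 0.34. Both were therefore among the genes set apart as shared with other classes. Trem2 (ENSMUSG00000023992, GRCm38 chromosome 17, 48346401 to 48354147) stood at 938 against 858 counts per 1000000 UMIs (CPM) in macrophage-like cells (0.13, -0.019, 0.10), a ratio with an interval of 1.05 to 1.14, and at 1327 against 1268 in the foamy-like state (0.065, -0.14, 0.12). Tyrobp (ENSMUSG00000030579, chromosome 7, 30413760 to 30417585) stood at 2132 against 1972 in macrophage-like cells (0.11, 0.17, -0.066) and 2614 against 2528 in the foamy-like state (0.048, 0.16, -0.12). Ldlr (ENSMUSG00000032193, chromosome 9, 21723483 to 21749919) stood at 5.85 against 7.55 and 3.07 against 7.24, and its 3' tags can lie outside the deleted part of the gene. Outside macrophages Trem2 was low, at 2.48 against 1.51 in contractile and 21.4 against 20.9 in modulated smooth-muscle-like cells, 6.80 against 1.64 in fibroblast-like and 4.52 against 3.03 in T cell-like cells. Endothelial-like cells had 18 Trem2 UMIs in the agonist library (11.4 CPM), 6 of them in 1 cell, and 0 in the isotype library, where 3 counts would be 2.63 CPM. Tyrobp outside macrophages was 5.70 against 3.05, 8.88 against 7.23, 19.5 against 6.20, 37.5 against 7.01 and 17.3 against 9.60 CPM in contractile, modulated, fibroblast-like, endothelial-like and T cell-like cells, with 40.7% and 34.8% of the agonist UMIs of the last classes in 1 cell, and Ldlr 5.70 against 4.89, 3.13 against 3.99, 6.24 against 8.20, 1.90 against 2.63 and 0.754 against 2.02.

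In macrophage-like cells the agonist library had more RNA of Apoc1, an apolipoprotein, and less of the resident macrophage receptors Cd163 and Lyve1. What differed in aortic macrophages was the question here. The genes furthest higher were Apoc1 (1.45, 1.56, 0.51), Timp1 (1.05, 1.42, 0.48), Rrad (0.86, 0.69, 0.57), Col2a1 (0.84, 0.37, 0.97), Tia1 (0.72, 1.62, 0.19) and Spsb1 (0.67, 0.53, 0.80). Apoc1 (ENSMUSG00000040564, chromosome 7, 19689481 to 19692660) stood at 26.3 against 8.96 CPM and Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527) at 70.3 against 133. Apoc1 was not confined to macrophages: it was at 0.72 in the other classes pooled, just short of the rule that sets such genes apart. Timp1 encodes an inhibitor of matrix metalloproteinases, and Col2a1 a cartilage collagen also high in modulated smooth-muscle-like cells. Those furthest lower were Cd226 (-1.02, -1.34, -0.77), Il1rl1 (-0.95, -0.47, -0.98), Cd163 (-0.91, -0.91, -0.37), Mamdc2 (-0.89, -0.93, -0.97), Fgfr1 (-0.85, -0.75, -1.22) and Lyve1 (-0.83, -0.59, -0.72). Il1rl1 is the receptor of interleukin 33. The resident-like state held most UMIs of Cd163 and Lyve1 and the cavity-like state those of Cd226, and as pooled both took smaller shares in the agonist library. By sex their ratios were 1.00 and 0.944 and, in the cavity-like state, 0.610 and 0.976 in female-called and male-called cells, so the smaller resident-like share was hardly seen within either sex. Within the resident-like state the values were Cd163 (-0.61, -0.80, -0.21), Lyve1 (-0.54, -0.48, -0.59) and Il1rl1 (-0.94, -0.27, -2.53), and in the cavity-like state Cd226 (0.0061, -0.60, 0.019) and Il1rl1 (-0.74, -0.66, -0.84).

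Some large differences rested in part on single cells, which Poisson intervals do not cover. For these genes 1 more value, last in the brackets, leaves out, in each library, the cell with most UMIs of the gene. Among higher genes, 1 cell held at least 25% of the UMIs of S100a9 (3.46, -0.041, few, 2.66), S100a8 (2.28, 0.75, 2.75, 1.67), Chil3 (1.84, 4.58, few, 0.70) and Ccl5 (1.52, 0.068, few, 1.48). Chil3 was at -0.37 under the looser cell filter and -0.38 with at most 5% mitochondrial UMIs. Among lower genes, the same held for Cxcl13 (-3.25, -2.98, -3.24, -2.84), Sdk2 (-3.02, -4.06, few, -0.31), Kntc1 (-2.94, -2.81, few, -0.66) and Mfge8 (-1.05, 0.14, -2.51, -0.77).

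As a list, MHC class II genes were higher and resident macrophage genes lower in agonist macrophage-like cells. 6 of 9 MHC class II genes were higher (0.20, 0.32, 0.58), counting interval 0.026 to 0.28, at percentile 99.99 of matched random lists, with H2-DMb2 -0.84, H2-Ob 0.35, H2-Ab1 0.34 and H2-Eb1 0.32. They were higher in other classes too, at 0.65 in contractile and 0.99 in endothelial-like cells, but not in T cell-like cells, at -0.31, or in the cavity-like state (-0.20, -0.60, -0.22). 16 of 19 resident macrophage genes were lower (-0.38, -0.40, -0.24), led by Cd163 -0.91, Lyve1 -0.83, Cbr2 -0.65 and F13a1 -0.64, and within the resident-like state the list was at (-0.12, -0.30, -0.21). 11 of 16 genes of cholesterol efflux and LXR targets were higher (0.068, 0.070, 0.12), counting interval 0.015 to 0.16, percentile 98, led by Apoc1 1.45, Apoc2 0.60, Apoe 0.44 and Lpcat3 -0.31. 11 of 15 genes of lipid uptake and storage were lower (-0.16, -0.15, -0.38), led by Fabp4 -0.73, Cd36 -0.58, Acsl1 0.48 and Lpl -0.43.

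Of the other lists fixed for macrophages, cholesterol synthesis had the median furthest from 0, with a counting interval that held 0. Of the foamy lipid-associated genes 14 of 23 were higher (0.012, -0.019, -0.069), counting interval -0.0088 to 0.048, with Apoc1 1.45, Ctsl -0.60, Cd36 -0.58 and Gpnmb -0.51. 13 of 19 genes of TREM2 signalling were lower (-0.055, -0.13, -0.082), counting interval -0.12 to -0.0028, with Card9 -0.26 and Mapk1 -0.25, and their median was 0.022 with edgeR's TMM factor. 13 of 20 genes of inflammatory cytokines and NF-kB were lower (-0.071, -0.45, 0.087), counting interval -0.12 to -0.026, with Clec4e -0.78 and Cxcl1 -0.49, and their median was 0.0065 with the TMM factor. The remaining medians were cholesterol synthesis (-0.16, -0.050, -0.085) at percentile 10.5, with Stard4 -0.93 and Mvk -0.60; lysosome (0.0081, 0.0012, -0.074) at percentile 55.5, with Ctsl -0.60 and Ctsk -0.58; inflammasome (0.0085, -0.050, 0.16) at percentile 85.2, with Il1b 0.26 and Naip5 -0.25; and matrix proteases (-0.014, 0.026, 0.018) at percentile 68.4, with Timp1 1.05 and Mmp9 -0.68. Interferon response genes were at (-0.063, 0.13, 0.11) at percentile 44.3, with Oasl1 -1.70 and Ifit2 -0.73, and efferocytosis genes at (-0.020, -0.047, -0.072) at percentile 45.2, with Mfge8 -1.05 and Cd36 -0.58.

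Outside the main question, the median lay among the highest 2.5% of matched random lists for complement (0.13, 0.048, 0.21) with Serping1 0.69 and C3 0.39, T cell activation (0.21, 0.063, 0.18) with Ccl5 1.52 and Cxcr3 0.79 and oxidative phosphorylation (0.049, 0.051, 0.043) with Ndufs3 0.24 and Sdha -0.20. It was so too for genes typical of mesenchymal cells: TGF-beta targets (0.26, 0.22, 0.38) with Tgfb3 1.12 and Id3 0.57, chondrogenic genes (0.19, 0.38, 0.25) with Ibsp 1.51 and Chad 1.13, collagens (0.14, 0.15, 0.41) with Col4a2 -0.60 and Col1a1 0.54, smooth muscle modulation (0.13, 0.10, 0.40) with Timp1 1.05 and Tnfrsf11b 0.47 and smooth muscle contractile genes (0.072, 0.12, 0.094) with Lmod1 -0.62 and Mustn1 0.52. Chemokines were lower (-0.20, -0.15, 0.0047), with Cxcl13 -3.25 and Ccl5 1.52.

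MHC class II was higher in the agonist library in both foamy-like clusters, as in the resident-like and, more so, inflammatory-like but not cavity-like state. In foamy-like cells 7 of 7 genes were higher (0.62, 0.81, 1.13), counting interval 0.52 to 0.70, with Ciita (0.97, 2.09, few), H2-Ab1 (0.73, 1.08, 1.28), H2-Eb1 (0.69, 1.14, 1.64) and Cd74 (0.62, 0.77, 1.13). H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419) stood at 778 against 469 CPM, and Ciita encodes the transactivator of this gene family. 11 of 15 genes of lipid uptake and storage were lower (-0.30, -0.20, -0.46), led by Fabp4 (-0.83, -0.69, -1.44), Lpl (-0.46, -0.20, -0.68), Scarb1 (-0.45, -0.67, -0.21) and Hilpda (-0.41, 0.19, -0.72). 15 of 20 inflammatory and NF-kB genes were lower (-0.17, -0.26, -0.37), counting interval -0.27 to -0.037, with Clec4e -0.85, Il1a -0.65, Cxcl2 -0.63 and Cxcl1 0.54, but their median was 0.28 with at most 5% mitochondrial UMIs. 14 of 23 foamy lipid-associated genes were lower (-0.059, -0.080, -0.19), counting interval -0.079 to -0.0081, with Apoc1 (0.90, 1.87, -0.21), Ctsl (-0.78, -0.19, -1.28), Gpnmb (-0.62, -0.32, -1.06) and Atp6v0d2 (-0.56, -0.48, -0.75), and their median was 0.043 in thinned cells. Of the state, state cluster 2 made up 58.6% against 49.2%, ratio 1.19 (0.993 to 1.43), so part of these differences may go with the mix of its clusters. Within state clusters 2 and 3, MHC class II was at (0.44, 0.75, 1.17) and (0.77, 0.41, 1.61), and lipid uptake and storage at (-0.057, -0.24, 0.12), interval -0.48 to 0.017, and (-0.13, -0.12, -0.27), interval -0.25 to -0.029. Inflammatory and NF-kB genes were at (-0.076, -0.41, 0.14) and (-0.16, -0.17, -0.44) there, and Mfge8 at (0.70, 1.46, 1.65) and (-1.80, -1.09, -2.88).

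The other main lists in the foamy-like state were efferocytosis (0.084, -0.062, 0.10) at percentile 98.1, with Mfge8 -1.20 and Axl 0.65; matrix proteases (-0.12, -0.041, -0.13) at percentile 2.04, with Timp1 0.87 and Mmp19 -0.83; inflammasome (-0.14, -0.29, -0.15) at percentile 7.27, with Il18 0.40 and Il1b -0.39; and cholesterol efflux (0.079, 0.11, 0.058) at percentile 95.7, with Apoc1 0.90 and Apoc2 0.44. Cholesterol synthesis lay at (-0.17, -0.056, -0.28) at percentile 11.2, with Insig1 -0.62 and Dhcr7 0.47, and TREM2 signalling at (-0.064, -0.20, -0.011) at percentile 14.6, with Btk -0.54 and Pik3cg -0.39. Interferon response lay at (0.10, 0.14, 0.17) at percentile 88.7, with Isg15 1.06 and Irf7 -0.82, and lysosome at (-0.0057, -0.0060, -0.12) at percentile 21.7, with Ctsl -0.78 and Ctsk -0.61. The efferocytosis median was -0.0052 in thinned cells. Beside them, NRF2 antioxidant genes (-0.14, -0.028, -0.11) with Gclm -0.42 and Cat -0.39 were lower. Higher were smooth muscle modulation (0.41, 0.10, 0.43) with Vcam1 0.98 and Timp1 0.87, chondrogenic genes (0.25, 0.28, 0.66) with Ibsp 2.25 and Col2a1 1.16 and endothelial activation (0.24, 0.13, 0.16) with Vcam1 0.98 and Cxcl1 0.54.

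Single genes furthest higher in the foamy-like state were Fstl1 (1.34, 1.60, 1.03), Col2a1 (1.16, 0.27, few), Spsb1 (1.13, 0.88, 0.74), Psip1 (0.97, 0.44, 1.00) and Pmepa1 (0.93, 0.44, 1.69). Those furthest lower were Mamdc2 (-1.07, -1.84, -0.69), Ccnd3 (-1.0, -1.75, -0.56), Nabp1 (-0.91, -0.80, -1.10), Sgms2 (-0.87, -1.16, -1.43) and Clec4e (-0.85, -0.88, -1.29). Sgms2 encodes a sphingomyelin synthase. Mgl2 (-1.43, -1.0, few) and the chemokine Ccl12 (-1.06, -1.09, 1.36) were lower too, but under the looser cell filter they were at 2.18 and 0.96. Clec4e was at 0.37 with at most 5% mitochondrial UMIs. Genes with at least 25% of their UMIs in 1 cell, with that value last, were Ccl5 (4.21, few, few, 2.94), Ibsp (2.25, 0.29, few, 0.31), Agbl3 (1.92, 3.72, few, 0.48), Tia1 (1.45, 2.80, 0.72, 0.79) and Vcam1 (0.98, 0.86, few, 0.67), and, lower, Sdk2 (-3.60, -4.84, few, 0.045), Gse1 (-1.28, -1.28, 0.55, 0.0045), Mfge8 (-1.20, 0.16, -2.80, -0.88), Phactr2 (-0.98, -0.031, -0.26, -0.16) and Cacna1a (-0.93, -1.19, few, -0.36). Ccl5 had 181 UMIs against 3, a ratio interval of 10.0 to 146. In thinned cells Tia1, Vcam1 and Gse1 were at -0.40, -0.44 and 0.033.

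**Figure D2:**
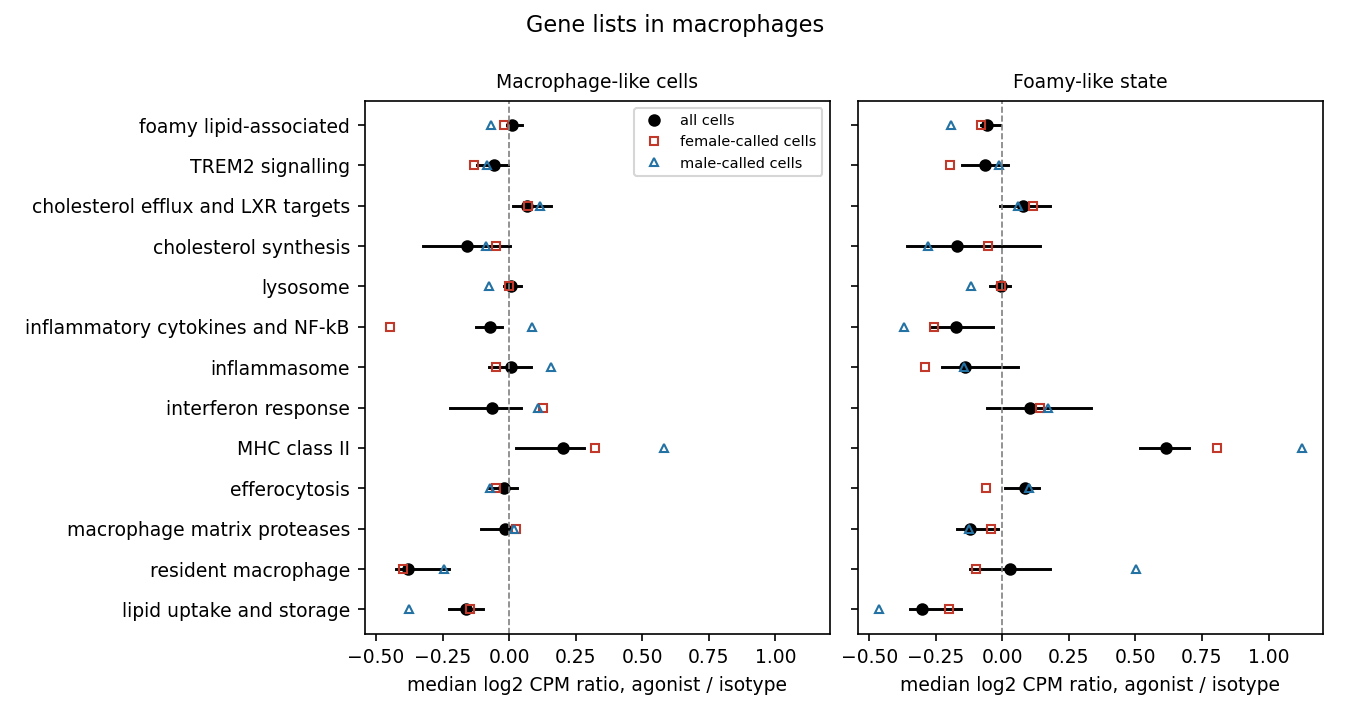
Median log2 CPM ratio, agonist over isotype, of 13 gene lists in macrophage-like cells and in their foamy-like state; black points with counting intervals are all cells, open symbols female-called and male-called cells. MHC class II lay at 0.20 and 0.62, and lipid uptake and storage at -0.16 and -0.30.

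Contractile genes were higher in the agonist library in modulated, but hardly in contractile, smooth-muscle-like cells. Smooth muscle makes the collagen of the plaque's cap, so the next question was its state. In modulated cells 23 of 23 contractile genes were higher (0.34, 0.29, 0.13), counting interval 0.30 to 0.41, led by Pln (1.04, 0.80, 1.74), Cnn1 (0.82, 0.98, 0.62), Actg2 (0.75, 1.50, 0.23) and Des (0.67, 1.64, 0.46). Their median was 0.054 under the looser cell filter. 16 of 22 chondrogenic and osteogenic genes were higher (0.25, 0.39, 0.34), counting interval 0.13 to 0.30, led by Mia (1.2, 1.2, 1.06), Chad (0.97, 0.40, 1.77), Ibsp (0.61, 0.61, 1.05) and Alpl (0.59, 0.82, 2.18), and part of this may go with the mix of clusters. Of the class, cluster 7, led by cartilage genes, made up 29.4% against 25%, ratio 1.18 (1.05 to 1.32), with 1.53 and 1.22 by sex. Within clusters 4 and 7 the chondrogenic list was at (-0.17, -0.066, 0.078) and (0.25, 0.029, 0.39), and the contractile list at (0.41, 0.54, 0.23) and (0.31, 0.17, 0.46). 14 of 19 genes of smooth muscle modulation were lower (-0.16, -0.24, -0.18), counting interval -0.18 to -0.15, led by Mmp3 (-0.68, -0.29, 0.48), Timp1 (0.27, 0.049, -0.021), C3 (-0.27, -0.41, -0.13) and Dcn (-0.23, -0.30, -0.20). 14 of 19 collagens were higher (0.10, 0.27, -0.019), counting interval 0.056 to 0.13, percentile 96.3, with Col18a1 0.31, Col5a3 0.29, Col4a1 0.28 and Col4a2 0.27, but the median was -0.044 under the looser cell filter and -0.052 with at most 5% mitochondrial UMIs.

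The modulated genes furthest higher were Mia (1.2, 1.2, 1.06), Snorc (1.13, 1.81, 1.48), Chad (0.97, 0.40, 1.77) and Ucma (0.93, 1.38, 1.17), all of cartilage. In cluster 4 alone Mia, Snorc and Chad were at 0.36, 0.38 and -0.059, and in cluster 7 alone at 1.14, 0.93 and 0.80. Those furthest lower were Ccbe1 (-1.68, -2.22, -1.02), Slpi (-1.57, -1.25, -0.28) and Igfbp6 (-0.99, -1.42, -0.28), and Saa1 (-1.0, -0.49, 0.91), at -0.68 without 1 cell. Other lists that stood out were collagen processing (0.096, 0.20, 0.035) with Loxl2 0.35 and Sparc 0.25, TGF-beta targets (0.11, 0.081, 0.082) with Acta2 0.57 and Tgfbi -0.37, oxidative phosphorylation (0.093, 0.040, 0.045) with Ndufv1 0.19 and Sdhc 0.18, fatty acid oxidation (0.063, -0.063, 0.068) with Acaa2 0.27 and Ech1 0.20 and MHC class II (0.21, 1.30, 0.72) with H2-Eb1 0.50 and H2-Ab1 0.38. Interferon response (0.093, -0.16, 0.31) with Usp18 0.74 and Isg15 0.51 and chemokines (0.11, -0.23, 0.42) with Ccl8 0.45 and Ccl4 0.39 were higher. Inflammatory and NF-kB genes were lower (-0.11, -0.30, 0.045), with Il1b 1.43 and Nos2 -0.92. Chemokines were at -0.26 and collagen processing at -0.039 with at most 5% mitochondrial UMIs. Median depth was 7697 against 4383 UMIs.

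In contractile smooth-muscle-like cells 15 of 23 contractile genes were higher (0.039, -0.021, 0.056), counting interval 0.019 to 0.051, percentile 78.8, with Des 0.21 and Tagln 0.19. 14 of 18 collagens (0.071, 0.12, 0.0081), 12 of 17 chondrogenic genes (0.080, 0.12, -0.030) and 14 of 19 modulation genes (0.051, -0.027, 0.076) were higher, with Col8a1 -0.28 and Col16a1 0.21, Chad 1.03 and Col2a1 0.85, and Mmp3 -0.55 and C3 0.38. The modulation median was -0.17 with at most 5% mitochondrial UMIs. Single genes furthest higher were Col2a1 (0.85, 1.45, 0.66), Tnr (0.70, -0.20, 0.21) and Dbp (0.69, -0.33, 1.4), and furthest lower Fkbp5 (-1.70, -2.02, 0.010), Grem2 (-1.10, -0.13, -0.67) and Nxph1 (-0.92, -0.87, 0.059). Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527) stood at 11.7 against 40.4 CPM. Dbp is an output gene of the circadian clock and Fkbp5 is induced by glucocorticoids. Cluster 13 of this class was led by the stress genes Atf3, Fos and Irf1, and the agonist library had more cells in the deeper cluster 1 (2492 against 1965) and fewer in the shallower cluster 0 (2268 against 2899).

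Further lists higher in contractile cells were TGF-beta targets (0.11, 0.060, -0.089) with Tgfbi 0.43 and Ccn2 0.40, elastic fibre genes (0.067, 0.090, 0.021) with Mfap2 0.52 and Fmod 0.42, glycolysis (0.076, 0.061, 0.0034) with Pdk1 -0.24 and Eno1 0.21 and chemokines (0.27, 0.17, 0.097) with Ccl8 1.09 and Ccl4 0.69. So were lists of macrophage genes, which smooth muscle should carry little of: MHC class II (0.65, 0.78, 0.89) with H2-Eb1 0.82 and H2-Ab1 0.69, complement (0.15, 0.12, 0.18) with C1qa 0.92 and C1qb 0.82, foamy genes (0.099, 0.13, 0.16) with Apoc1 0.79 and Gpnmb 0.68, lysosome (0.050, 0.079, 0.029) with Ctsk 0.44 and Cd68 0.44, matrix proteases (0.060, 0.12, 0.0046) with Mmp3 -0.55 and Ctsk 0.44 and T cell activation (0.24, 0.23, 0.073) with Ccl5 0.50 and Cd44 0.24. Chemokines and matrix proteases were at -0.17 and -0.020 with at most 5% mitochondrial UMIs.

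**Figure D3:**
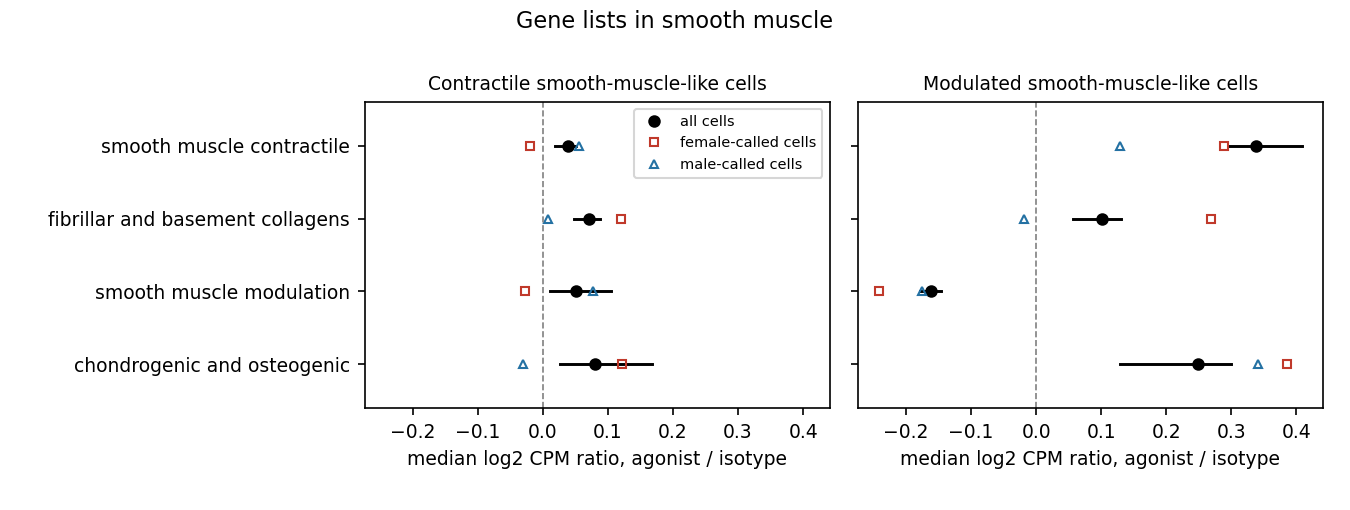
Median log2 CPM ratio, agonist over isotype, of the lists fixed for smooth muscle in contractile and modulated smooth-muscle-like cells; black points with counting intervals are all cells, open symbols female-called and male-called cells. The contractile list lay at 0.039 in contractile and 0.34 in modulated cells, where it was 0.054 under the looser cell filter.

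In fibroblast-like cells, asked about collagen and matrix, the collagen median was higher in the agonist library in female-called but not male-called cells. This was untested, and part may go with the mostly female-called cluster 25. 13 of 19 collagens were higher (0.17, 0.24, -0.17), counting interval 0.12 to 0.23, led by Col12a1 (0.99, 2.14, -1.01), Col8a1 (0.51, 1.31, -0.68), Col3a1 (0.45, 0.55, 0.55) and Col1a1 (0.41, 0.61, 0.33). Without cluster 25 the median was 0.067, not run by sex. Col1a1 and Col3a1 were higher in both sexes. 16 of 20 genes of collagen processing were higher (0.14, 0.13, 0.073), counting interval 0.077 to 0.19, with Loxl3 0.51, Pcolce2 -0.43, Lox 0.38 and Sparc 0.25. 11 of 22 elastic fibre and proteoglycan genes were higher (0.0020, -0.16, 0.029), counting interval -0.013 to 0.042, percentile 51.3, with Aspn 0.50, Emilin1 0.48, Eln -0.45 and Mfap2 0.41. Single genes furthest higher were Cyp26a1 (3.17, 4.13, few), Nt5e (2.82, 4.07, few), Kif26b (2.52, 3.42, 1.12), Hs6st2 (2.23, 3.09, few) and Ctla2a (2.03, 2.66, -0.088), of which Cyp26a1 also leads cluster 25. Without that cluster Nt5e, Kif26b, Hs6st2 and Ctla2a were at 0.60, 0.89, 0.024 and 1.65. Slpi (2.74, 2.61, few) had 44.1% of its UMIs in 1 cell. Those furthest lower were Ralyl (-1.47, -0.78, -3.20), Mrgprg (-1.36, -1.93, few), Fam13a (-1.08, -1.18, -0.31) and Hs6st3 (-1.04, -1.06, -2.07).

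Interferon response genes were lower in fibroblast-like cells, 22 of 24 (-0.31, -0.48, 0.53), with Rsad2 -1.96 and Ifi44 -1.22. Higher were glycolysis (0.37, 0.60, 0.23) with Slc16a3 1.31 and Pdk1 0.73, NF-kB genes (0.34, 0.63, -0.0065) with Cxcl2 1.82 and Il1b 1.58, smooth muscle modulation (0.25, 0.60, 0.28) with Spp1 1.48 and Timp1 1.2, chondrogenic genes (0.31, 0.096, 0.045) with Spp1 1.48 and Chad 0.99 and repair and growth factors (0.19, 0.35, 0.31) with Spp1 1.48 and Hbegf 1.44. The chondrogenic median was -0.072, -0.10 and -0.13 under the looser cell filter, with at most 5% mitochondrial UMIs and with no doublets removed. Also higher were endothelial activation (0.23, 0.16, -0.076) with Sele 2.51 (70 UMIs against 3, ratio interval 4.69 to 70.9) and Esm1 -2.02, chemokines (0.22, 0.26, 0.58) with Cxcl2 1.82 and Ccl9 1.73, oxidative phosphorylation (0.050, 0.063, -0.0066) with Uqcrq 0.24 and Cycs 0.23 and cholesterol efflux (0.13, -0.029, 0.14) with Apoc1 1.25 and Ch25h 0.91. Macrophage genes were higher too: foamy genes (0.23, 0.22, 0.51) with Trem2 1.56 and Spp1 1.48, TREM2 signalling (0.22, 0.23, 0.24) with Trem2 1.56 and Tyrobp 1.51, MHC class II (0.39, 0.027, 3.15) with H2-Eb1 0.69 and Cd74 0.46, complement (0.28, -0.19, 0.59) with C1qb 1.36 and C1qa 1.33 and lysosome (0.10, 0.072, 0.050) with Ctss 0.78 and Cd68 0.75. In this and other classes such genes may be RNA from other cells. Without cluster 25, repair and growth factors were at -0.0069 and TREM2 signalling at -0.036. TREM2 signalling was at -0.026 over genes with at least 200 UMIs, MHC class II at -0.14 in thinned cells, and smooth muscle modulation at -0.047 with at most 5% mitochondrial UMIs.

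In endothelial-like cells the activation genes, such as Vcam1 and Sele, showed no common direction between sexes. 9 of 17 were higher (0.032, 0.27, -0.092), counting interval -0.029 to 0.24, percentile 72.5, with Apln 1.30, Vcam1 0.61, Edn1 0.52 and Lrg1 0.42. The genes furthest lower were Adamts9 (-1.41, -2.17, few) and Tcim (-1.20, -2.20, 0.70), with Ubr2 and Tom1 at -1.74 and -1.12, or -0.31 and -0.20 without 1 cell each. Those furthest higher were mostly leukocyte genes with at least 25% of UMIs in 1 cell, with the value without that cell last, C1qb (3.92, few, few, 3.63), C1qa (3.65, few, few, 3.73), Lyz2 (2.97, few, few, 2.13), Lcn2 (1.61, -0.19, 1.62, 1.54) and Cxcl2 (1.38, 0.081, 2.01, 0.34). Under the looser cell filter Cxcl2 was at -0.53.

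Lists higher in endothelial-like cells were MHC class II (0.99, 0.45, 1.23) with H2-Eb1 1.24 and H2-Aa 1.15, MHC class I (0.15, 0.49, 0.35) with H2-Q4 0.64 and Tap2 -0.58, complement (0.44, 0.78, 0.51) with C1qb 3.92 and C1qc 3.80 (78 UMIs against 3, ratio interval 6.22 to 93.4), lysosome (0.14, 0.083, 0.30) with Ctss 2.88 and Gba -0.94 and foamy genes (0.17, -0.13, 0.36) with Lgals3 1.11 and Spp1 0.94. Others were smooth muscle modulation (0.29, -0.13, 0.92) with Lgals3 1.11 and C3 0.95, repair and growth factors (0.21, 0.032, 0.45) with Tgfbi 1.09 and Spp1 0.94, collagens (0.19, -0.032, 0.93) with Col14a1 1.26 and Col6a1 -0.79, matrix proteases (0.14, -0.22, 0.39) with Ctss 2.88 and Plaur -0.44 and chemokines (0.23, -0.19, 1.03) with Ccl5 (75 UMIs against 0) and Cxcl2 1.38. T cell activation (3.02, -0.18, 3.12) rested on 2 genes, Ccl5 and Cd44, and its size depends on the pseudocount because Ccl5 had 0 isotype UMIs. Complement was at -0.14 over genes with at least 200 UMIs, and smooth muscle modulation at -0.039 in thinned cells. Lower were interferon response (-0.22, 0.026, 0.092) with Ifit3 -0.89 and Stat2 -0.82 and naive T cell genes (-0.22, -0.31, -0.40) with S1pr1 -0.39 and Actn1 -0.22.

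T cell-like cells of the agonist library had more RNA of activation genes such as Pdcd1, which encodes PD-1, in 1 of their 2 clusters. Their activation was the question here. 12 of 15 activation genes were higher (0.75, 0.97, 0.77), counting interval 0.58 to 0.89, with Pdcd1 (2.23, 2.63, 1.84), Tnfrsf9 (1.23, 1.34, 1.55), Ccl5 (-1.20, -1.20, -1.63) and Cxcr6 (1.00, 1.23, 0.77). 8 of 10 naive and memory genes were lower (-0.12, -0.31, -0.18), counting interval -0.24 to -0.040, percentile 6.80, with Actn1 -0.55, Il7r 0.34, Dapl1 -0.32 and Sell -0.27. Of the class, cluster 20 made up 39.3% against 27%, ratio 1.45 (1.2 to 1.76), so part of the difference may go with the mix of clusters. Within cluster 20 activation genes were at (0.83, 0.99, 0.033), interval 0.56 to 0.97, with Pdcd1 (2.46, 2.91, 1.24) and Tnfrsf9 (1.79, 2.05, 0.72), and naive and memory genes at (-0.58, -0.79, -0.0094). Within cluster 10 they were at (-0.094, -0.15, 0.37), interval -0.31 to 0.11, and (0.12, 0.059, 0.046). The genes furthest higher were Pdcd1, Bcl2a1d (2.17, 1.32, 2.42), Clnk (1.77, 1.56, 1.36), Ramp3 (1.72, 1.01, 3.71), Cd163l1 (1.70, 2.04, 0.80) and Tnfsf11 (1.62, 1.43, 1.96). Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553) stood at 58.1 against 11.6 CPM. Cd163l1 also leads cluster 20, and Tnfsf11 encodes RANKL. Those furthest lower were Lgr6 (-1.56, few, -0.079), Olfr1033 (-1.36, -1.68, 0.26), Ogn (-1.31, -1.68, 0.61), Postn (-1.29, -1.70, 0.43), Nox4 (-1.28, -1.38, 0.099) and Erbb4 (-1.27, -1.16, -0.12), genes of mesenchymal cells in part, and Olfr1033 and Ogn were at 0.11 and 0.091 with no doublets removed.

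Mesenchymal lists were lower in agonist T cell-like cells as pooled but not in male-called cells or in cluster 10 alone: contractile genes (-0.79, -0.80, 0.17) with Lmod1 -1.06 and Mustn1 -1.05, collagens (-0.50, -0.45, 0.14) with Col15a1 -1.07 and Col18a1 -0.93, elastic fibre genes (-0.36, -0.56, 0.64) with Ogn -1.31 and Fbln5 -0.97, collagen processing (-0.28, -0.63, 0.28) with Plod2 -0.74 and Serpinh1 -0.57 and TGF-beta targets (-0.24, -0.53, 0.61) with Postn -1.29 and Ccn1 -1.04. With no doublets removed they were at 0.13, 0.30, 0.27, 0.26 and 0.25. Chemokines were lower (-0.48, -1.65, -0.19), with Ccl5 -1.20 and Cxcl2 -0.55, and at 0.42 with no doublets removed. Higher were NF-kB genes (0.31, -0.14, 0.50) with Tnf 0.75 and Ptgs2 0.63, glycolysis (0.14, 0.071, 0.082) with Hk2 0.67 and Pgam1 -0.59, unfolded protein response (0.15, 0.13, 0.42) with Sdf2l1 0.89 and Pdia6 0.60, cholesterol efflux (0.20, 0.10, 0.33) with Apoe 0.82 and Abca1 0.45, immediate early genes (0.12, -0.24, 0.57) with Hsph1 -0.81 and Junb 0.78 and complement (1.13, 0.0084, -0.26) with C1qc 2.15 and C1qa 1.70. Complement was at -0.14 over genes with at least 200 UMIs, NF-kB genes at -0.21 in cluster 10 alone, and immediate early genes at -0.11 and -0.17 in clusters 10 and 20 alone.

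Some genes differed in the same direction in the other classes pooled, by at least 0.5 times as much. Uba52, a fusion of ubiquitin and a ribosomal protein, was higher in macrophage-like, foamy-like, contractile, modulated and endothelial-like cells, at (1.42, 1.48, 1.31), (1.32, 1.38, 1.43), (1.48, 1.45, 1.47), (1.44, 1.46, 1.35) and (1.54, 1.21, 1.84). Gstp1 was higher in macrophage-like, foamy-like and contractile cells (0.84, 1.2, 1.04), (0.93, 1.47, 1.31) and (0.73, 0.65, 0.59), as were Bloc1s1 in contractile (0.79, 0.76, 0.70) and Cxcl5 in modulated cells (1.01, 1.37, 2.07). Zbtb16 was lower in contractile, modulated, fibroblast-like and endothelial-like cells (-1.11, -1.33, -0.25), (-1.61, -2.21, -0.56), (-2.01, -2.37, -0.33) and (-1.81, -1.25, -0.32). Fkbp5 was lower in macrophage-like cells (-1.55, -1.90, 0.0035), Pdk4 in contractile (-0.81, -1.04, 0.39) and Ano4 in fibroblast-like cells (-1.34, -0.72, few). Igfbp3 was lower in endothelial-like cells (-1.42, -4.41, 0.88, -1.04), with the value without 1 cell last, and at 0.0053 under the looser cell filter. H2-Ab1, 0.34 in macrophage-like cells, was at 0.23 in the other classes pooled. Tsix, antisense to Xist, was lower in macrophage-like, contractile and modulated cells (-1.94, -0.58, few), (-1.54, -0.037, few) and (-1.68, -0.10, few). Ribosomal protein genes were higher in macrophage-like, foamy-like, contractile, modulated and fibroblast-like cells (0.14, 0.22, 0.066), (0.14, 0.27, 0.15), (0.088, 0.044, 0.076), (0.13, 0.15, 0.12) and (0.092, 0.14, 0.13). Mitochondrially encoded genes were lower in the first 4 of these, (-0.15, -0.12, -0.023), (-0.13, -0.15, 0.080), (-0.11, -0.081, -0.11) and (-0.15, -0.053, -0.12). Haemoglobin genes, carried by red cells, were at (0.79, -0.27, 3.07) in macrophage-like, (1.13, 0.69, 3.68) in foamy-like, (0.30, 0.32, 0.70) in contractile and (1.36, 0.51, 3.87) in T cell-like cells, and with no doublets removed at -0.35 in macrophage-like cells.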

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

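All tests of explanations in this part were chosen after the results were seen, except that the alternatives of cell filter, doublet removal and clustering were set beforehand. Among classes of cells, 3 shares stood out because their ratio lay on opposite sides of 1 in female-called and male-called cells with both intervals excluding 1, and the difference between the sexes was not tested. B cell-like cells had ratios of 1.88 (1.48 to 2.39) and 0.577 (0.444 to 0.752) in female-called and male-called cells. Cluster 21, led by Arpp21, Rag1 and Dntt, had 0.234 (0.104 to 0.463) and 4.83 (2.69 to 9.54), from 9 against 98 female-called and 164 against 12 male-called cells. Cells in clusters without a name had 0.746 (0.633 to 0.876) and 1.2 (1.01 to 1.43). Single clusters were not searched for this, but cluster 2 of contractile cells met it too, at 0.690 and 1.45. The labels name no mice, so these values may reflect differences between mice as much as between sexes.

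Fkbp5, Zbtb16, Tsc22d3 and Pdk4, genes that glucocorticoids induce, were picked because they were lower in the agonist library in contractile, modulated and fibroblast-like cells, with a median of -0.85 (-0.96 to -0.78), while 14 other glucocorticoid genes were lower in 35 of 42 values, median -0.18 (-0.24 to -0.14). In female-called cells these genes stood at -1.11 (-1.31 to -1.0), but they were picked as lower. There the 14 others stood at -0.36 (-0.46 to -0.32), 36 of 42 values lower. This argues against a different mix of female and male cells as the whole cause there. In male-called cells 17 of 42 were lower, median 0.078. Another hour of harvest stays open. Clock output genes minus genes of the opposite phase stood at -0.46 (-0.56 to -0.15) in female-called and 0.95 (0.68 to 1.15) in male-called contractile cells. These opposite directions cannot decide it. The antibody cannot be told apart from this, as treatment goes with library and animals. The picked genes stood at -0.24 (-0.38 to -0.10) in male-called cells, 8 of 12 values lower. A candidate explanation is therefore that mice, or the hour of harvest, differed between the libraries, and the labels give neither.

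The macrophage-like share was larger in the agonist library, ratio 1.39 (1.28 to 1.50). A lower yield of smooth muscle would raise every other class alike. A macrophage-like ratio of 1.23 (1.13 to 1.33) among cells outside smooth muscle argues against it as the whole cause. It may be part: fibroblast-like, endothelial-like, monocyte-like and NK-like cells had ratios of 1.24, 1.24, 1.23 and 1.51. The T cell-like ratio (0.638, 1.05 in female-called cells) cannot decide this, as carried-over lymphoid tissue may have lowered it. A different mix of sexes is argued against by ratios of 1.43 (1.24 to 1.63) and 1.45 (1.21 to 1.74) in female-called and male-called cells. Cell filter, doublet removal and clustering are argued against as the whole cause by a lowest ratio of 1.30 over 6 prespecified alternatives, with at most 5% mitochondrial UMIs. The antibody remains open, and so do differences between mice, dissections or libraries, because each treatment had 1 library.

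The T cell-like share was smaller in the agonist library, ratio 0.638 (0.571 to 0.712), or 0.809 with cluster 21 counted in. A different mix of sexes is argued against as the whole cause by a ratio of 0.385 (0.316 to 0.469) in male-called cells. Lymphoid tissue around the aorta carried into the isotype library stays open, since in male-called cells cluster 10, led by Lef1, had a ratio of 0.282 (0.224 to 0.355) and B cell-like cells 0.577 (0.444 to 0.752), while cluster 20, led by Il17a, had 1.05 (0.669 to 1.69). Plasma-cell-like cells, at 0.25 (0.114 in male-called cells), go with it. Against it, B cell-like cells had a ratio of 1.13 pooled and 1.88 in female-called cells. The antibody cannot be told apart from lymphoid tissue because treatment goes with library and animals, and the ratio was 1.05 (0.854 to 1.29) in female-called cells.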

How the results depend on the processing

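Values in female-called or male-called cells, without the cell with most UMIs of each gene, without cluster 25, and in cluster 4, 7, 10 or 20 or state cluster 2 or 3 alone, the T cell-like share with cluster 21, and the macrophage-like share of cells outside smooth muscle were chosen after the data were seen, and all other alternatives were set beforehand. No paired analysis was possible because each group had 1 library, and replicate numbers only name samples in accession order. A value reversed when it changed direction although its interval had excluded no difference, and otherwise moved when it lay outside that counting interval.

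The larger macrophage-like share and the higher MHC class II and T cell activation lists kept their direction under every prespecified alternative run for them. The macrophage-like ratio was 1.30 to 1.52 over 6 prespecified alternatives. The median of MHC class II was 0.12 to 0.49 over 10 in macrophage-like cells and 0.29 to 0.73 over 11 in foamy-like cells, and that of T cell activation in T cell-like cells 0.55 to 0.86 over 10. In the values added later the first 3 ranged over 1.23 to 1.45, 0.22 to 0.58 and 0.44 to 1.13, while T cell activation did not keep its direction, at -0.094 to 0.97, with the lowest value in cluster 10 alone. Contractile genes in modulated cells kept their direction too, at 0.054 to 0.38 over 10 prespecified and 0.13 to 0.41 over 5 added alternatives.

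Others kept it under the prespecified alternatives but not in one of the added ones. The T cell-like ratio was 0.560 to 0.857 over 6 prespecified alternatives, the modulated ratio 0.817 to 0.984, and the median of chondrogenic genes in modulated cells 0.11 to 0.31. Collagens in fibroblast-like cells were at 0.12 to 0.22, Trem2 in macrophage-like cells at 0.026 to 0.21 over 8, and contractile genes in contractile cells at 0.014 to 0.079. The fibroblast-like ratio, 1.24 as reported, was 1.00 to 1.15 over 6 prespecified alternatives, so its size depended on each of these. The share ratio of the foamy-like state was 0.903 to 1.08 over 7, the list of foamy genes -0.060 to 0.090 in macrophage-like and -0.18 to 0.043 in foamy-like cells, and endothelial activation -0.018 to 0.14, with no direction kept. The share of cells with a Trem2 UMI had ratios of 1.08 to 1.15 with other thinning, and that with a Gpnmb UMI 0.891 to 1.04, where the highest value used no thinning and therefore the deeper agonist cells.

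Of the values of class shares under prespecified alternatives, 42 stayed within the counting interval, 25 moved beyond it and 3 reversed. Of the list medians 929 stayed, 280 moved and 39 reversed. Of the named genes in macrophage-like cells 148 stayed, 57 moved and 2 reversed, and in foamy-like cells 167 stayed, 57 moved and 9 reversed. In T cell-like cells 78 stayed, 16 moved and 2 reversed, and in endothelial-like cells 76 stayed, 15 moved and 5 reversed. Smooth muscle and fibroblast genes had 65 and 48 moved values and no reversed one there. Among the values added later, of list medians 259 stayed, 177 moved and 48 reversed.

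The values that reversed, and those of the main comparisons that moved, follow by alternative. Ratios are given for shares and log2 ratios for lists (as medians) and genes. For each of these values, the cause was not tested. Under the looser cell filter, the ratio of shares moved for macrophage-like cells (1.52), modulated cells (0.984), fibroblast-like cells (1.15), T cell-like cells (0.560) and the foamy-like state (0.903). Foamy genes (-0.020), NF-kB genes (-0.13) and MHC class II (0.46) in macrophage-like cells, foamy genes (-0.084) in foamy-like cells, and contractile genes (0.054) in modulated cells moved. Collagens (-0.044) in modulated cells, chondrogenic genes (-0.072) in fibroblast-like cells, and collagens (0.27), collagen processing (0.15), elastic fibre genes (0.23) and TGF-beta targets (0.21) in T cell-like cells reversed. Chil3 (-0.37) in macrophage-like cells, Mgl2 (2.18) and Ccl12 (0.96) in foamy-like cells, and Cxcl2 (-0.53) and Igfbp3 (0.0053) in endothelial-like cells reversed. With at most 5% mitochondrial UMIs, the ratio of shares moved for contractile cells (0.987), fibroblast-like cells (1.00) and the foamy-like state (0.908), and lay on the other side of 1 for monocyte-like cells (0.986). Foamy genes (-0.060) and MHC class II (0.49) in macrophage-like cells, and foamy genes (-0.18) and MHC class II (0.73) in foamy-like cells moved. Trem2 (0.026) in macrophage-like cells moved. NF-kB genes (0.28) in foamy-like cells, chemokines (-0.17), matrix proteases (-0.020) and smooth muscle modulation (-0.17) in contractile cells, and chemokines (-0.26), collagens (-0.052) and collagen processing (-0.039) in modulated cells reversed. Chondrogenic genes (-0.10) and smooth muscle modulation (-0.047) in fibroblast-like cells, and collagen processing (0.10) in T cell-like cells reversed. Chil3 (-0.38) in macrophage-like cells, and Mgl2 (3.62), Ccl12 (1.50) and Clec4e (0.37) in foamy-like cells reversed. With no doublets removed, the ratio of shares moved for modulated cells (0.835), fibroblast-like cells (1.09) and T cell-like cells (0.722). Foamy genes (-0.053) and NF-kB genes (-0.14) in macrophage-like cells, MHC class II (0.42) in foamy-like cells, and contractile genes (0.12) in modulated cells moved. T cell activation (0.55) in T cell-like cells moved. Haemoglobin genes (-0.35) in macrophage-like cells, collagens (-0.027) in modulated cells, and chondrogenic genes (-0.13) in fibroblast-like cells reversed. Chemokines (0.42), contractile genes (0.13), collagens (0.30), collagen processing (0.26), elastic fibre genes (0.27) and TGF-beta targets (0.25) in T cell-like cells reversed. Olfr1033 (0.11) and Ogn (0.091) in T cell-like cells reversed. With each library clustered on its own, the ratio of shares moved for modulated cells (0.817) and fibroblast-like cells (1.09), and lay on the other side of 1 for contractile cells (1.02) and endothelial-like cells (0.759). At Leiden resolution 0.5, the ratio of shares moved for fibroblast-like cells (1.11) and T cell-like cells (0.857). At Leiden resolution 2, the ratio of shares moved for modulated cells (0.820) and fibroblast-like cells (1.08).

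With the median-of-ratios factor, foamy genes (0.064) and NF-kB genes (-0.019) in macrophage-like cells, and contractile genes (0.062) in contractile cells moved. With edgeR's TMM factor, foamy genes (0.090) in macrophage-like cells, and contractile genes (0.079) in contractile cells moved. Trem2 (0.21) in macrophage-like cells moved. TREM2 signalling (0.022) and NF-kB genes (0.0065) in macrophage-like cells reversed. As means over cells, foamy genes (0.056), NF-kB genes (-0.17) and MHC class II (0.30) in macrophage-like cells, MHC class II (0.29) in foamy-like cells, and contractile genes (0.30) in modulated cells moved. Matrix proteases (-0.0089) in contractile cells, and MHC class II (-0.14) in fibroblast-like cells reversed. Vcam1 (-0.12) in foamy-like cells, and Cxcl2 (-0.25) in endothelial-like cells reversed. With each cell thinned to 1000 UMIs, foamy genes (-0.030) in macrophage-like cells, MHC class II (0.42) in foamy-like cells, contractile genes (0.014) in contractile cells, and chondrogenic genes (0.31) in modulated cells moved. Foamy genes (0.043) and efferocytosis (-0.0052) in foamy-like cells, MHC class II (-0.14) in fibroblast-like cells, and smooth muscle modulation (-0.039) in endothelial-like cells reversed. Tia1 (-0.40), Vcam1 (-0.44) and Gse1 (0.033) in foamy-like cells, and Cxcl2 (-0.030) and Igfbp3 (0.067) in endothelial-like cells reversed. With a pseudocount of 10 CPM, contractile genes (0.29) and chondrogenic genes (0.11) in modulated cells moved. Without a minimum for list members, MHC class II (-0.0061) in fibroblast-like cells, and chemokines (0.052) in T cell-like cells reversed. With a minimum of 200 UMIs, chemokines (-0.048) in contractile cells, TREM2 signalling (-0.026) in fibroblast-like cells, complement (-0.14) in endothelial-like cells, and complement (-0.14) in T cell-like cells reversed. With macrophage-like cells with a UMI of both Trem2 and Gpnmb taken as the foamy-like ones, MHC class II (0.72) in foamy-like cells moved.

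In female-called cells, the ratio of shares moved for contractile cells (0.876), modulated cells (0.719) and fibroblast-like cells (1.68), and lay on the other side of 1 for T cell-like cells (1.05). Foamy genes (-0.019), NF-kB genes (-0.45) and MHC class II (0.32) in macrophage-like cells, and foamy genes (-0.081) and MHC class II (0.81) in foamy-like cells moved. Contractile genes (0.29) and chondrogenic genes (0.39) in modulated cells, collagens (0.24) in fibroblast-like cells, endothelial activation (0.27) in endothelial-like cells, and T cell activation (0.97) in T cell-like cells moved. Haemoglobin genes (-0.27) in macrophage-like cells, efferocytosis (-0.062) in foamy-like cells, contractile genes (-0.021) and smooth muscle modulation (-0.027) in contractile cells, and chemokines (-0.23) in modulated cells reversed. Cholesterol efflux (-0.029) and complement (-0.19) in fibroblast-like cells, and foamy genes (-0.13), interferon response (0.026), collagens (-0.032), smooth muscle modulation (-0.13) and T cell activation (-0.18) in endothelial-like cells reversed. NF-kB genes (-0.14) and immediate early genes (-0.24) in T cell-like cells reversed. S100a9 (-0.041), Mfge8 (0.14) and Trem2 (-0.019) in macrophage-like cells, Mfge8 (0.16) in foamy-like cells, and Tnr (-0.20) and Dbp (-0.33) in contractile cells reversed. Lyz2 (-0.51) and Lcn2 (-0.19) in endothelial-like cells reversed.

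In male-called cells, the ratio of shares moved for contractile cells (0.944) and T cell-like cells (0.385), and lay on the other side of 1 for modulated cells (1.01), NK-like cells (0.888) and Schwann-like cells (1.94). Foamy genes (-0.069) and MHC class II (0.58) in macrophage-like cells, foamy genes (-0.19) and MHC class II (1.13) in foamy-like cells, and contractile genes (0.056) in contractile cells moved. Contractile genes (0.13) and chondrogenic genes (0.34) in modulated cells, and endothelial activation (-0.092) in endothelial-like cells moved. NF-kB genes (0.087) and chemokines (0.0047) in macrophage-like cells, mitochondrially encoded genes (0.080) in foamy-like cells, and chondrogenic genes (-0.030) and TGF-beta targets (-0.089) in contractile cells reversed. NF-kB genes (0.045) and collagens (-0.019) in modulated cells, and oxidative phosphorylation (-0.0066), NF-kB genes (-0.0065), interferon response (0.53), collagens (-0.17) and endothelial activation (-0.076) in fibroblast-like cells reversed. Interferon response (0.092) in endothelial-like cells, and contractile genes (0.17), collagens (0.14), collagen processing (0.28), elastic fibre genes (0.64), TGF-beta targets (0.61) and complement (-0.26) in T cell-like cells reversed. Sdk2 (1.49), Fkbp5 (0.0035) and Tyrobp (-0.066) in macrophage-like cells, and Sdk2 (3.05), Mgl2 (3.14), Gse1 (0.55), Ccl12 (1.36) and Cacna1a (1.63) in foamy-like cells reversed. Fkbp5 (0.010), Nxph1 (0.059) and Pdk4 (0.39) in contractile cells, Saa1 (0.91) in modulated cells, and Ctla2a (-0.089), Mrgprg (2.72) and Ano4 (2.64) in fibroblast-like cells reversed. Igfbp3 (0.88), Adamts9 (4.98) and Tcim (0.70) in endothelial-like cells, and Olfr1033 (0.26), Ogn (0.61), Postn (0.43) and Nox4 (0.10) in T cell-like cells reversed. In these cells the isotype library had 0 UMIs of Ano4, of Adamts9, and of Mgl2 and Sdk2 in the foamy-like state, 1 of Mrgprg and of Sdk2 in macrophage-like cells, and 3 of Cacna1a, so the size of these values depends on the pseudocount.

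Without the cell with most UMIs of each gene, foamy genes (0.055) in macrophage-like cells, and foamy genes (-0.0009) in foamy-like cells moved. Sdk2 (0.045) and Gse1 (0.0045) in foamy-like cells reversed. Without cluster 25, collagens (0.067) in fibroblast-like cells moved. TREM2 signalling (-0.036) and repair and growth factors (-0.0069) in fibroblast-like cells reversed. In cluster 4 alone, contractile genes (0.41) in modulated cells moved. Chondrogenic genes (-0.17) in modulated cells reversed. Chad (-0.059) in modulated cells reversed. In state cluster 2 alone, MHC class II (0.44) in foamy-like cells moved. Foamy genes (0.047) in foamy-like cells reversed. Ibsp (-0.23), Agbl3 (-0.67), Sdk2 (1.04) and Mfge8 (0.70) in foamy-like cells reversed. In state cluster 3 alone, MHC class II (0.77) in foamy-like cells moved. Ccl12 (0.066) in foamy-like cells reversed. In cluster 10 alone, NF-kB genes (-0.21), contractile genes (0.036), collagens (0.37), collagen processing (0.12), elastic fibre genes (0.39), TGF-beta targets (0.22) and T cell activation (-0.094) in T cell-like cells reversed. T cell naive and memory (0.12) and immediate early genes (-0.11) in T cell-like cells reversed. Ramp3 (-0.28) and Ogn (0.41) in T cell-like cells reversed. In cluster 20 alone, unfolded protein response (-0.090) and immediate early genes (-0.17) in T cell-like cells reversed. With cluster 21 counted as T cell-like, the ratio of shares moved for T cell-like cells (0.809). Among cells outside smooth muscle, the ratio of shares moved for macrophage-like cells (1.23).

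Some alternatives gave no value: no cluster was named NK at resolution 0.5, and none plasma cell with each library clustered on its own. Kntc1 in macrophage-like and Agbl3 in foamy-like cells had fewer than 10 UMIs once thinned, and T cell activation in endothelial-like cells had no gene with 200 UMIs. The same held for Ibsp in foamy-like cells in either sex, C1qa and C1qb in female-called endothelial-like cells, Kntc1, Tsix and Cyp26a1 in male-called cells, and Cyp26a1 without cluster 25. The number of cells limits values within a sex: male-called cells of the isotype library numbered 154 macrophage-like, 42 endothelial-like and 200 T cell-like cells. Apart from this, the isotype library was shallower, at a median of 2681 UMIs per cell against 3377.5, so a gene seen in 1 library alone was read against 3 counts.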

Other observations

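The remaining classes had no comparison of their own, so their lists are given as values. In monocyte-like cells, with median depths of 3072 UMIs in the agonist and 2287 in the isotype library, repair and growth factors were higher (0.62, 0.68, 0.59), with Pdgfa (1.94, 0.94, few), Thbs1 (1.71, 2.40, 1.87) and Spp1 (1.38, 0.68, 2.21). Chemokines were at (0.53, 0.65, 0.66) with Ccl7 (2.70, -0.32, 1.37) and Ccl2 (1.27, -0.67, 1.48), glycolysis at (0.23, 0.42, 0.45) with Hif1a (0.69, 1.26, 1.03) and Gapdh (0.52, 0.49, 0.56), and NF-kB genes at (0.18, 0.61, 0.45) with Ptgs2 (1.15, 2.09, 1.27) and Osm (1.03, 1.04, 0.53). MHC class II was at (0.21, 0.54, -0.54), complement at (0.16, 0.26, 0.68) and MHC class I at (-0.22, -0.18, 0.080).

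In NK-like cells, at median depths of 2155 and 2777 UMIs, 20 of 38 lists lay among the lowest or highest 2.5% of matched random lists. Chemokines were higher (1.28, 1.03, 1.47), with Ccl3 (1.42, 1.30, 1.91) and Ccl4 (1.28, 1.03, 1.47), and T cell activation was at (0.28, -0.044, 0.51) with Pdcd1 (1.30, 1.52, 1.05) and Gzmb (0.77, 0.53, 1.76). Naive and memory genes were lower (-0.45, -0.11, -0.58), with Sell (-1.49, 0.10, -2.06) and Satb1 (-1.03, -1.08, -1.18). Genes typical of mesenchymal cells were higher: contractile genes (0.86, 0.87, 1.28), collagens (0.81, 0.66, 1.26), elastic fibre genes (0.84, 0.79, 0.91), chondrogenic genes (0.76, 0.67, 0.63) and TGF-beta targets (0.42, 0.20, 0.82).

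B cell-like cells had median depths of 1994 and 2144 UMIs. Oxidative phosphorylation was at (0.15, 0.21, 0.19), cholesterol synthesis at (0.50, 0.76, 0.73) with Srebf2 (0.50, 0.58, 0.73) and Hmgcr (0.49, 0.94, 0.73), and immediate early genes at (-0.26, -0.83, 0.28) with Hspa1a (-1.22, -2.85, -0.62) and Hsph1 (-1.19, -2.58, -0.53). Chemokines were lower (-2.48, -3.96, -2.06), but 57.1% of the UMIs of Ccl5 were in 1 cell.

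MHC class II was higher in the inflammatory-like state too, at (0.89, 1.42, 0.91), 7 of 7 genes higher. Of that state, state cluster 4 made up 33.8% against 23.9%, ratio 1.42 (1.09 to 1.85), and within state clusters 0 and 4 the list was at (0.71, 0.99, 0.49) and (0.39, 0.28, 0.44). It was at (0.40, 0.48, 1.57) in the resident-like state, 7 of 7 higher, and at (-0.20, -0.60, -0.22) in the cavity-like state, 1 of 8 higher.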
